A study of Arabidopsis thaliana with 4 samples.

How the data were processed

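Bent cotyledon-stage Arabidopsis seeds of lec1-1 plants with a LEC1-GFP transgene were fixed with formaldehyde, and the chromatin was sonicated to fragments of 100 to 500 bp, per the labels' protocols. An anti-GFP antibody gave the ChIP libraries and unprecipitated chromatin gave the input libraries, each amplified with 15 PCR cycles, per the labels' protocols. There were 2 biological replicates of each, per the series' design text. The submitters' processing notes name the TAIR10 genome build, Bowtie 0.12.7 and SAMtools 0.1.19. The peak caller, its threshold, the treatment of duplicates and multiply mapping reads, and whether the replicates were pooled are not given in the sources used here.

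The deposited data used are 1 peak list for the series with a position, a running number and a value for each peak. The values were read as a score made by the authors, whose scale and base are not given in the sources used here, and they served only to describe and rank peaks within the list. Scores fell with the running number (Spearman's rho -0.98 across peaks). All 6356 starts lay on a 50 bp grid and all ends 1 bp before a grid line, so peak edges are no finer than the grid. Starts were raised by 1 to print positions counted from 1. With no values per sample, neither the ChIP and input libraries nor the replicates could be compared here, and the depth of each library is unknown.

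Gene positions and symbols came from a RefSeq gene table of assembly TAIR10.1, whereas the notes name TAIR10. The match was checked by moving the peaks by fixed offsets: the share of midpoints inside genes was lowest without an offset (34.0%) and was 64.0% and 62.7% at 10000 bp to either side. In 24 of 25 chromosome segments, 5 per chromosome, the best offset lay within 200 bp of 0. Positions of genes are not printed. All 360 list members (358 distinct loci) were found in the table, 349 with the symbol given here and 11 by locus alone.

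The gene lists, the families, the tests of location, gene-poor windows, lists and families, and most alternatives were set before the data were examined. Tests of peak scores were not among them. The plan used 1000 bp upstream of transcription start sites, shares in exons, introns and untranslated regions, and motif tests. The table gives neither strand nor exons and no genome sequence was used here, so the flank of 1000 bp outside either end of each gene replaced the upstream window, and exon shares and motifs were not analysed here. Gene descriptions were replaced by symbols and synonyms for the family test, which left 24 of 26 families with at least 5 genes. The either-end flank was chosen after the gene table had been seen, and several flank widths had been looked at before the final calculation.

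A gene counted as bound with at least 1 bp of a peak in its flank, and 1 peak could count for several genes. Locations of peak midpoints were tested against 1000 circular shifts per chromosome, and the gene-poor 25% of 500 kb windows, partial windows at chromosome ends included, against 1000 uniform placements. Lists and families were tested with Fisher's exact test, two-sided, against all other protein-coding genes, with Benjamini-Hochberg adjustment over 17 lists or 24 families and a threshold of 0.05. Highest scores per bound gene were compared with 100000 random sets of bound genes of equal size (permutation test, two-sided), for lists with at least 3 bound members. The 17 lists were seed transcription regulators, storage proteins, oil body proteins, fatty acid and oil synthesis, late embryogenesis and desiccation, photosynthesis, gibberellin, abscisic acid, auxin, brassinosteroid, embryo patterning, NF-Y subunits, seed coat, endosperm, defence, root nutrient uptake and constitutive genes. Genes are treated as independent in these tests, although neighbours can share a peak.

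Genes named in the report followed a rule: LEC1, LEC2, FUS3, ABI3, L1L, WRI1, ABI5 and BZIP67 always, up to 3 bound members with the highest score and the first 2 unbound members of each list, and the genes at the 5 peaks with the highest scores. Other members of the lists that are named were chosen after their values were seen. Alternatives covered the 3178 peaks with the highest scores, removal of the widest 5%, flanks of 500 and 2000 bp, the gene body, stricter overlap, nearest gene only, other backgrounds, matched random lists, tandem genes counted once, 100 kb windows and uniform placement. Named genes as background and the gene body alone were added after the data were seen.

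The list test was tested on simulated data over 27444 genes with 100 runs. A list with peaks planted at its members with a probability of 60% was called in 69% of runs with 9 members and in 100% with 31 members. Peaks planted at other genes could also reach these members. Of lists not chosen for planting 0.692% were called higher, although the NF-Y list among them shares LEC1 and L1L with a planted list. With circularly shifted real peaks 0.353% of lists were called, in either direction. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.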

Results

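Chromatin immunoprecipitation followed by sequencing was used to locate the seed regulator LEAFY COTYLEDON1 (LEC1) on the Arabidopsis genome in bent cotyledon-stage seeds, when the embryo is filling with storage reserves. LEC1 is an NF-YB subunit of the NF-Y transcription factor complex and is required for normal embryo maturation. The plants were lec1-1 mutants carrying a transgene for LEC1 fused to green fluorescent protein (LEC1-GFP) between LEC1 flanking sequences. Fragments pulled down with an anti-GFP antibody (2 biological replicates) were set against input, the total fragmented chromatin of the same material (2 biological replicates). The data consist of 1 list of peaks for the whole series, so each value below describes that list and carries no replicate error. The read depth of the samples is unknown. Intervals are 95% exact binomial intervals and cover counting error only.

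The list held 6356 LEC1-GFP peaks on TAIR10 chromosomes 1 to 5, with 1713 on chromosome 1, 976 on chromosome 2, 1264 on chromosome 3, 970 on chromosome 4 and 1433 on chromosome 5. Set against gene content, the number ran from 22.6 peaks per 100 protein-coding genes on chromosome 2 to 23.9 on chromosome 1. Peaks were narrow, with a median width of 249 bp (interquartile range 149 to 349 bp) and a widest peak of 1649 bp. Together they covered 1654 kb. Scores, which are the authors' own values per peak on a scale not given in the sources used here, ran from 1.92 to 4.51 with a median of 2.45. Wider peaks had higher scores (Spearman's rho 0.86 across peaks, which are not independent replicates).

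The first question was where LEC1-GFP sat relative to genes. LEC1-GFP peaks gathered at the ends of protein-coding genes, on both sides of the end: 3137 of 6356 midpoints (49.4%, 48.1 to 50.6%) lay outside genes and within 1 kb of a gene end. Shifting all peaks along each chromosome gave 20.4% ± 0.663 (SD over 1000 shifts), so the share was 2.42-fold that of shifted peaks (permutation p = 0.002, two-sided, the smallest that 1000 shifts can give). The first 100 bp outside a gene end held 15.5% of peaks, against 3.57% for shifted peaks, and the first 100 bp inside held 14.0% against 4.86%. Gene bodies as a whole held 34.0% of midpoints (32.9 to 35.2%) against 54.2% for shifted peaks (permutation p = 0.002), and of the peaks inside genes 72.0% lay within 300 bp of an end. Intergenic sites farther than 1 kb from any protein-coding gene held 16.6% against 25.4% (permutation p = 0.004). These shifts also carry peaks into gene-poor regions, so the comparison partly reflects where on the chromosome peaks lie. With all peaks moved by 10000 bp to either side, such sites held 13.4% and 14.6%, below the 16.6% of the peaks. A lack of peaks at these sites is therefore not shown relative to nearby sequence. The share outside genes within 1 kb of an end was 22.6% at both offsets, still far below 49.4%. The gene table used carries no strand, so upstream and downstream ends were counted together and the shares do not separate promoters from 3′ flanks.

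**Figure D1:**
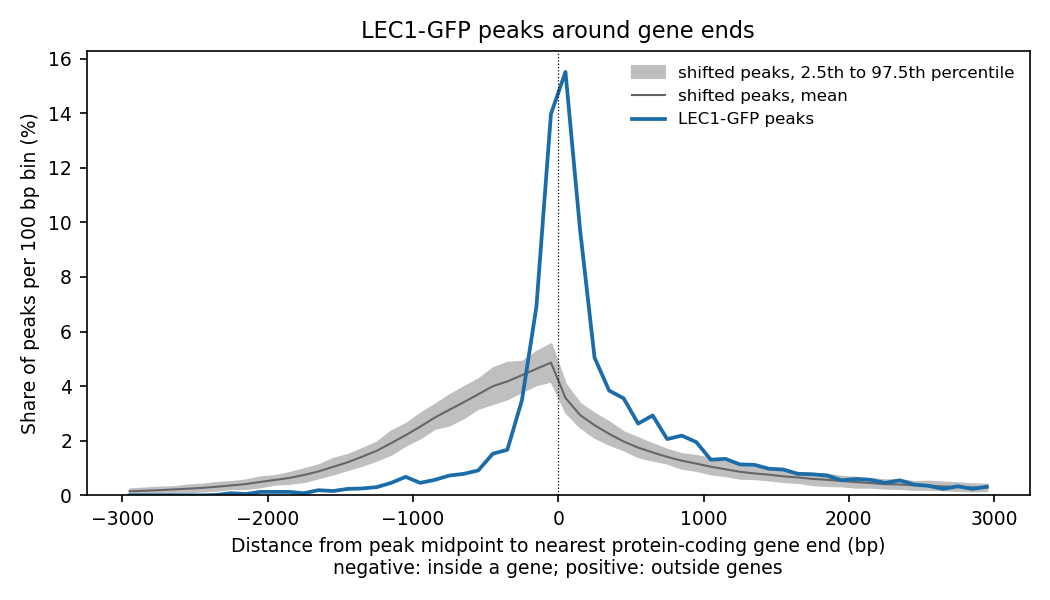
Share of LEC1-GFP peak midpoints (%) per 100 bp bin against the distance in bp to the nearest end of a protein-coding gene, negative inside genes and positive outside. The blue line is the 6356 peaks, the grey line and band are the mean and central 95% of shifted peaks, and the peaks reach 15.5% in the first bin outside gene ends against 3.57% for shifted peaks.

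Gene-poor chromosome regions, which in Arabidopsis lie mainly around the centromeres, held few LEC1-GFP peaks. The 25% of the genome with the fewest genes (60 of 240 windows of 500 kb) held 481 peaks, or 7.57% (6.93 to 8.25%). Randomly placed peaks put 24.4% there (permutation p = 0.002, two-sided, the smallest that 1000 placements can give). These windows contained 10.8% of all protein-coding genes. A peak in the 1000 bp outside either end was found at 319 of 2962 genes in these windows (10.8%, 9.68 to 11.9%) and at 5562 of 24482 genes in the remaining windows (22.7%, 22.2 to 23.2%). These intervals do not overlap, but they treat genes as independent although neighbours can share a peak. How multiply mapping reads were treated is not given in the sources used here, so the lower share is not shown to be less binding.

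**Figure D2:**
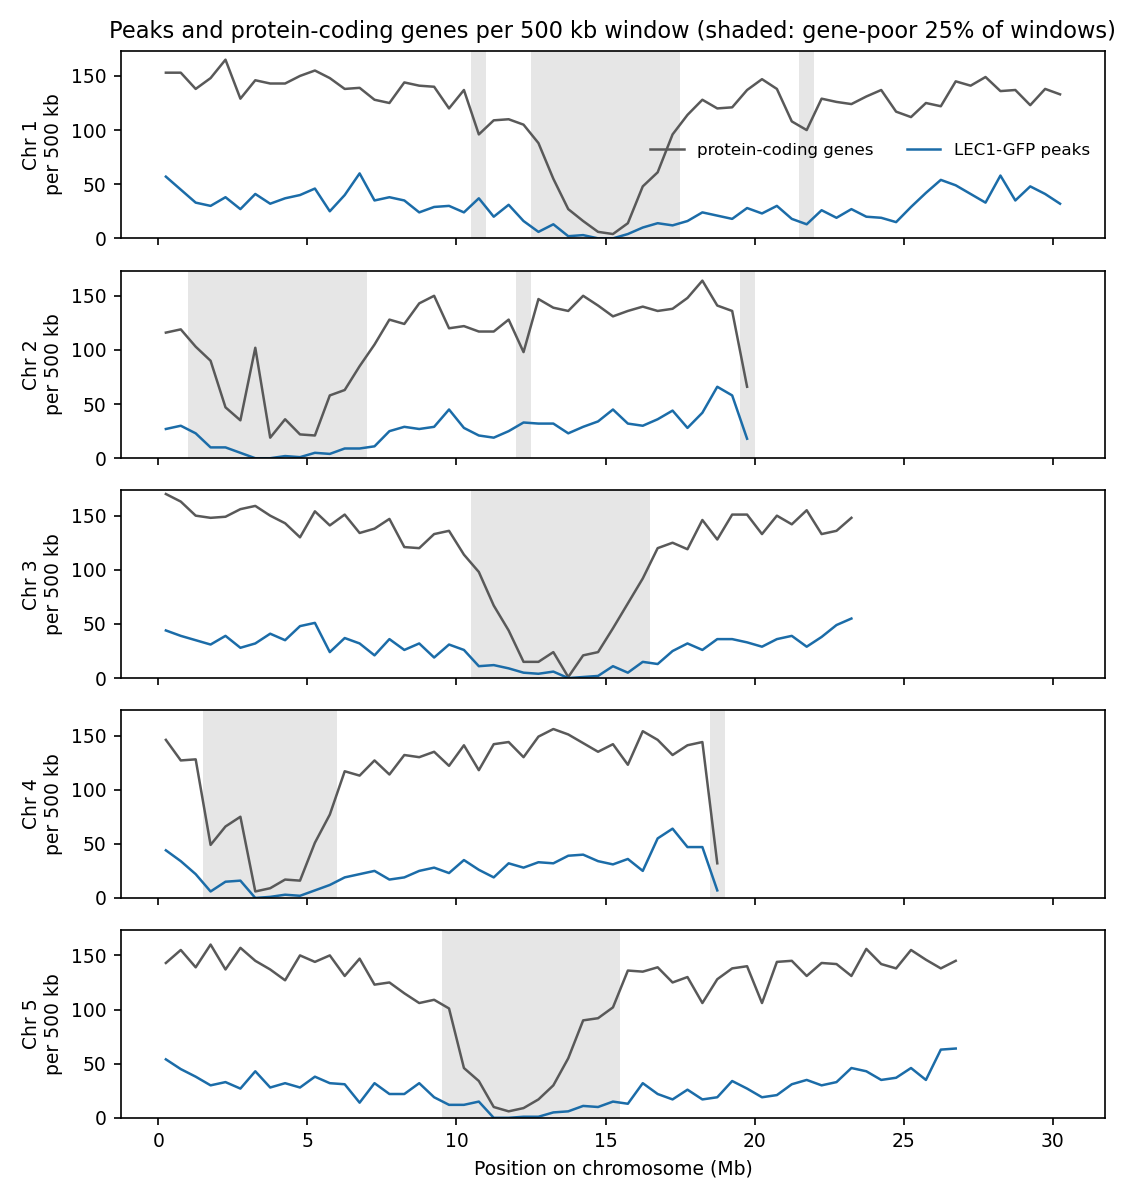
Number of LEC1-GFP peaks (blue) and of protein-coding genes (grey) per 500 kb window along chromosomes 1 to 5, with position in Mb and the 60 gene-poor windows shaded. The shaded windows together hold 7.57% of peaks and 10.8% of protein-coding genes, although some single shaded windows on chromosomes 1 and 2 hold more peaks than the windows beside them.

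Genes with at least 1 bp of a peak in the 1000 bp outside either end are called bound here. LEC1-GFP had 5881 bound genes among 27444 protein-coding genes (21.4%, 20.9 to 21.9%), whereas 100 sets of shifted peaks gave a mean of 3321 (2911 to 3677). The shifts also carry peaks into gene-poor regions, which can lower that mean. Most bound genes had 1 peak (5136), 687 had 2 and 58 had 3 or more. Of the peaks, 2762 lay at 1 gene and 1896 (29.8%) at 2 or more, so neighbouring genes could share a peak. With the gene body alone in place of the flanks 3432 genes had a peak, and the 3178 peaks with the highest scores gave 3323 bound genes.

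The second question was which genes LEC1-GFP occupied, asked with 17 gene lists fixed beforehand. Regulators of seed development were bound far more often than other genes: 16 of 26 (61.5%, 40.6 to 79.8%) had a peak, against 21.4% of the other protein-coding genes (Fisher's exact test, adjusted p = 9.38e-05). LEC2, a B3-domain regulator of embryo identity, had the highest score among them, 4.17 (chromosome 1, 9899751 to 9900249). The other B3 regulators of maturation were bound as well, FUS3 with a score of 3.59 (chromosome 3, 9855601 to 9856549) and ABI3 with a score of 3.08 (chromosome 3, 8996551 to 8996949). L1L, the closest relative of LEC1, had a score of 3.64 (chromosome 5, 19314701 to 19315149). BZIP67 and ABI5, bZIP factors of the abscisic acid response in seeds, had scores of 3.64 (chromosome 3, 16081751 to 16082399) and 3.41 (chromosome 2, 15207451 to 15207949). WRI1, which activates fatty acid synthesis genes, had a score of 2.96 (chromosome 3, 20114451 to 20114749). VAL2, a repressor of the embryo programme after germination, came next after LEC2 with a score of 4.07 (chromosome 4, 15485751 to 15486249). LEC1 itself had a narrow peak with a score of 2.17 (chromosome 1, 7729601 to 7729749). BBM and ABI4 had no peak. The bound regulators had a median highest score of 3.22 against 2.53 for all bound genes (permutation adjusted p = 0.0015), and no other list's scores differed after adjustment over the 15 lists tested. This score test was not part of the plan.

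Genes for the seed's protein reserves were mostly bound. Of 9 storage protein genes 7 had a peak (77.8%, 40.0 to 97.2%; Fisher's exact test, adjusted p = 0.00120). SESA1, a napin-type albumin, had a score of 3.62 (chromosome 4, 13607001 to 13607449). The cruciferin genes CRA1 and CRC had highest scores of 3.29 and 3.01, each with 2 peaks, and CRB had a score of 2.88. SESA3 and SESA4, neighbours in the albumin cluster, shared a peak with a score of 2.47, while SESA2 of the same cluster and PAP85 had none. Albumin genes of this cluster are similar copies, so the assignment of a peak among them is uncertain.

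Oil body protein genes had peaks at 6 of 9 members (66.7%, 29.9 to 92.5%; Fisher's exact test, adjusted p = 0.00942). Oleosins, which coat oil bodies, accounted for 4 of the 6, with scores of 2.92 at OLEO1 (chromosome 4, 12900151 to 12900499), 2.90 at OLEO5, 2.84 at OLEO3 and 2.34 at OLEO2. The caleosin genes ATS1 and CLO2 had scores of 2.31 and 2.23. OLEO4 and the steroleosin gene HSD1 had no peak. The call was lost with the 3178 highest-scoring peaks, where 33.3% of the list and 12.1% of other genes were bound (exact adjusted p = 0.145), and against named genes alone (exact adjusted p = 0.0574).

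Genes of fatty acid and oil synthesis were bound at 16 of 31 (51.6%, 33.1 to 69.8%; Fisher's exact test, adjusted p = 0.000584). PDH-E1 BETA, a subunit of plastid pyruvate dehydrogenase, had the highest score of the list, 3.26 (chromosome 1, 10586501 to 10586949). PDAT, an acyltransferase gene of oil assembly, had a score of 3.17 (chromosome 5, 4392101 to 4392499), from a peak shared with its neighbour GUN5. CAC1 and CAC3, subunits of acetyl-CoA carboxylase, had scores of 2.99 and 2.98. The fatty acid elongase FAE1 had a score of 2.55, and the desaturases FAD2 and FAD3 had 2.34 and 2.27. DGAT2 and ROD1 had no peak.

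Late embryogenesis and desiccation tolerance genes were bound at 13 of 22 (59.1%, 36.4 to 79.3%; Fisher's exact test, adjusted p = 0.000580). LEA4-5 and LEA4-1, late embryogenesis abundant proteins, had scores of 4.03 (chromosome 5, 2090301 to 2090749) and 3.78 (chromosome 1, 11774101 to 11774549). LEA14 had 2 peaks and a highest score of 3.42, and the galactinol synthase GOLS2 had a score of 3.17. EM1 and EM6 had no peak.

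Photosynthesis and chloroplast genes were bound often, and their list had the smallest p of the 17. Peaks were found at 50 of 65 genes (76.9%, 64.8 to 86.5%) against 21.3% of the other protein-coding genes, a ratio of 3.61 (Fisher's exact test, adjusted p = 3.18e-20). Peaks lay at 13 of 16 light-harvesting protein genes (81.2%, 54.4 to 96.0%), 10 of 12 photosystem I genes (83.3%, 51.6 to 97.9%) and 9 of 10 photosystem II genes (90%, 55.5 to 99.7%), parts that were chosen after the values were seen. PORC, an enzyme of chlorophyll synthesis, had a score of 3.48 (chromosome 1, 907251 to 907799). RBCS3B, a small subunit of Rubisco, had a score of 3.39 (chromosome 5, 15378351 to 15378749), and its neighbours RBCS1B and RBCS2B shared a peak with a score of 2.59. LHCB4.1 of the photosystem II antenna had a score of 3.28 (chromosome 5, 208651 to 209099). CAB3 and LHCB3 had no peak, and CAB3 lies beside its near-identical copies CAB1 and CAB2, which had scores of 3.18 and 2.05. With the peak midpoint required to lie in the flank, the share fell to 43.1%, against 17.8% of other genes (Fisher's exact test, adjusted p = 3.42e-05, and 2.63e-23 to 0.00113 over all 12 settings).

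**Figure D3:**
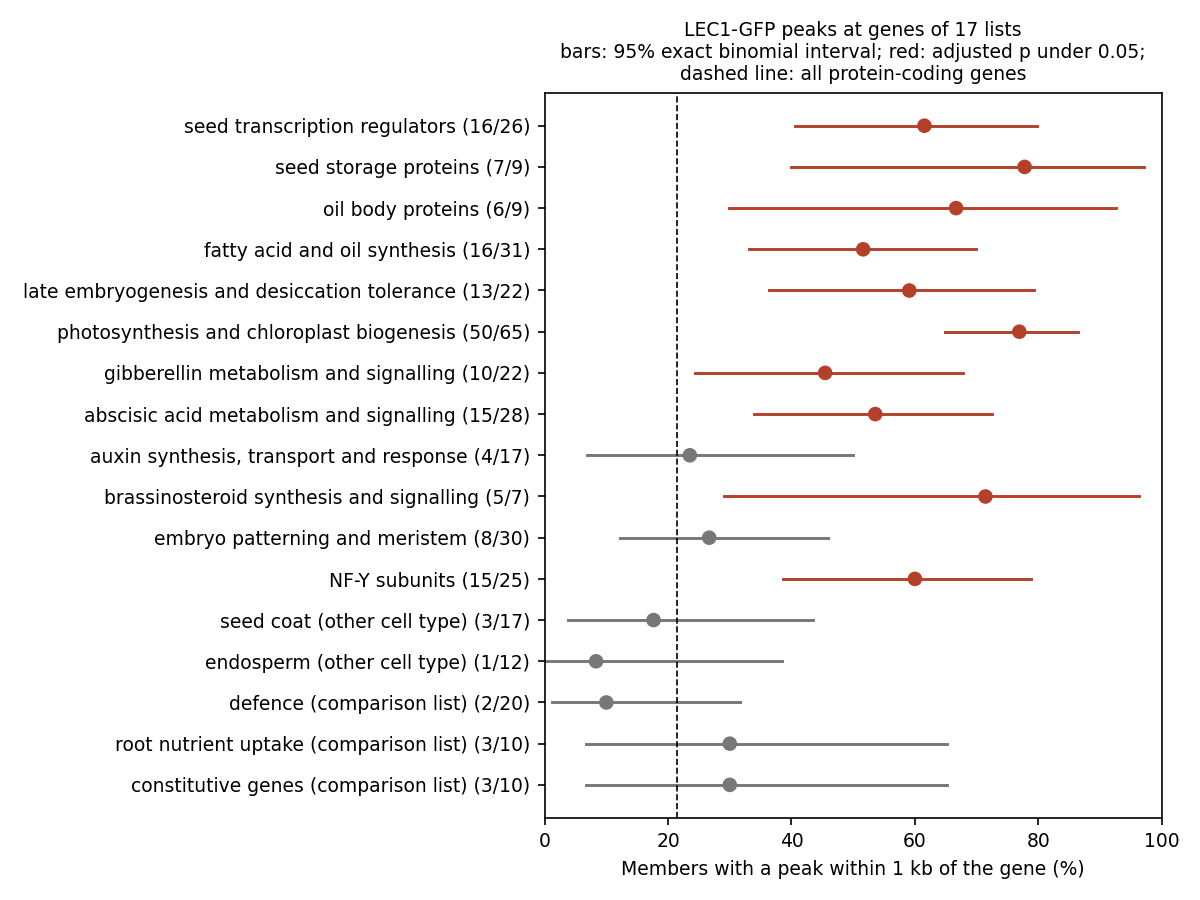
Share (%) of the genes of each of 17 lists with a LEC1-GFP peak in the 1 kb outside either end of the gene, with bound and total members in brackets; points are shares, bars are 95% exact binomial intervals and red marks an adjusted p under 0.05. The photosynthesis list stands at 76.9% and the storage proteins at 77.8%, to the right of the dashed line at 21.4% for all protein-coding genes, while the endosperm and defence lists stand at 8.33% and 10.0%.

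Among the hormone pathways, abscisic acid genes were bound at 15 of 28 (53.6%, 33.9 to 72.5%; Fisher's exact test, adjusted p = 0.000584). Within this list, peaks lay at 8 of 9 protein phosphatases 2C that restrain abscisic acid signalling (88.9%, 51.8 to 99.7%), a part chosen after the values were seen. AHG3 had the highest score, 3.57 (chromosome 3, 3585701 to 3586199), followed by HAI1 with 3.35 and HAB2 with 3.18. ABI1 had a score of 3.10 from a peak shared with its neighbour RPS2. All 3 genes for abscisic acid 8′-hydroxylases in the list, CYP707A1, CYP707A2 and CYP707A3, had a peak. Of the synthesis genes, NCED9 and NCED6 had scores of 2.302 and 2.08, and ABA1, ABA2, ABA3, AAO3, NCED3 and NCED5 had no peak. Of the receptor genes, PYL4 had a score of 2.14, and PYR1, PYL1, PYL5 and PYL6 had no peak.

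Gibberellin genes were bound at 10 of 22 (45.5%, 24.4 to 67.8%; Fisher's exact test, adjusted p = 0.0257). GA20OX3, a late synthesis enzyme, had a score of 3.54 (chromosome 5, 2246301 to 2247399), the receptor gene GID1B had 3 peaks and a highest score of 3.48, and GA3OX2 had a score of 3.07. Of the DELLA genes, which act in gibberellin signalling, 4 of 5 had a peak, with highest scores from 2.15 to 2.53, a part chosen after the values were seen. The synthesis genes GA3 and GA2 had scores of 2.81 and 2.59, and GA1, KAO1, GA20OX1, GA20OX2 and GA3OX1 had no peak. This call was lost in 6 of the 12 alternative settings tried, with adjusted p from 0.00515 to 0.422 over all of them.

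Brassinosteroid genes were bound at 5 of 7 (71.4%, 29.0 to 96.3%; Fisher's exact test, adjusted p = 0.0121). The synthesis enzyme gene DWF4 had a score of 2.84 (chromosome 3, 18817701 to 18817949) and the transcription factor genes BES1 and BZR1 had 2.66 and 2.47, while CPD and BIN2 had no peak. The call was lost with the 3178 highest-scoring peaks (42.9% bound against 12.1% of other genes, exact adjusted p = 0.0805). Auxin genes were bound at 4 of 17 (23.5%, 6.81 to 49.9%), which did not differ detectably from other genes (Fisher's exact test, adjusted p = 0.819). ARF2 had a score of 3.79 (chromosome 5, 24909551 to 24909949), IAA30 had 2.41 and YUC10 had 2.31, and YUC1 and YUC2 had no peak.

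Genes for NF-Y subunits, the family of LEC1, were bound at 15 of 25 (60%, 38.7 to 78.9%; Fisher's exact test, adjusted p = 0.000182). They comprised 7 of 10 NF-YA genes, 5 of 10 NF-YB genes and 3 of 5 NF-YC genes. NF-YB2 had a score of 3.57 (chromosome 5, 19308601 to 19309299) and NF-YC2 had a score of 3.44 (chromosome 1, 21024451 to 21024949). NF-YB6, which is L1L, and LEC1 also belong to the list of seed regulators. NF-YA5 and NF-YA6 had no peak. The call was lost when the peak midpoint had to lie in the flank (32.0% bound against 17.8% of other genes, exact adjusted p = 0.133).

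Embryo patterning and meristem genes were bound at 8 of 30 (26.7%, 12.3 to 45.9%), not detectably different from other genes (Fisher's exact test, adjusted p = 0.571). The corepressor gene TPL had a score of 2.88 (chromosome 1, 5421151 to 5421649), AS1 had 2.75 and SCR had 2.71. WOX2 and WOX8, early patterning genes, had no peak.

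Lists for other seed tissues and for other processes did not differ detectably from the rest of the genome. Seed coat genes were bound at 3 of 17 (17.65%, 3.80 to 43.4%; Fisher's exact test, adjusted p = 1), TTG2, PMEI6 and MUM2 with scores of 2.43, 2.25 and 2.08, and TT2 and TT8 had no peak. Endosperm genes were bound at 1 of 12 (8.33%, 0.211 to 38.5%; exact adjusted p = 0.571), ICE1 with a score of 2.73, and IKU2 and MINI3 had no peak. Defence genes were bound at 2 of 20 (10.0%, 1.23 to 31.7%; exact adjusted p = 0.436), RPS2 and BAK1 with scores of 3.10 and 2.16, and PR1 and BGL2 had no peak. Root nutrient uptake genes were bound at 3 of 10 (30.0%, 6.67 to 65.2%; exact adjusted p = 0.571), FRO2, NRT1.1 and SULTR1;2 with scores of 3.24, 3.16 and 2.41, and IRT1 and NRT2.1 had no peak. Constitutively expressed genes were also bound at 3 of 10 (30.0%; exact adjusted p = 0.571), GAPC1, UBQ10 and ACT7 with scores of 3.44, 2.79 and 2.55, and ACT2 and ACT8 had no peak. These lists are short, and in simulated data a list of 9 genes with peaks planted at 60% was called in 69% of 100 runs. That figure does not give the power to detect a smaller rise or a share below that of other genes.

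Gene families were also defined by words in gene names. Photosystem genes were bound at 32 of 45 (71.1%, 55.7 to 83.6%; Fisher's exact test, adjusted p = 3.16e-11), genes with chlorophyll in their name at 20 of 37 (54.1%, 36.9 to 70.5%; exact adjusted p = 0.000166) and light-harvesting genes at 7 of 8 (87.5%, 47.3 to 99.7%; exact adjusted p = 0.00108). These families can share genes with each other and with the photosynthesis list, so their calls are not separate evidence. Ethylene response or AP2 factors were bound at 56 of 165 (33.9%, 26.8 to 41.7%; exact adjusted p = 0.00112), late embryogenesis abundant genes at 7 of 11 (63.6%, 30.8 to 89.1%; exact adjusted p = 0.0144), heat shock genes at 19 of 52 (36.5%, 23.6 to 51%; exact adjusted p = 0.0440) and bZIP genes at 18 of 49 (36.7%, 23.4 to 51.7%; exact adjusted p = 0.0470). The other 17 of the 24 families tested did not pass, among them MYB domain genes (22.3%), WRKY genes (26.4%), protein kinases (22.9%) and ribosomal protein genes (16.4%). Zinc finger genes (35.0%, exact adjusted p = 0.0506) and NAC domain genes (30.9%, exact adjusted p = 0.0687) came closest and passed in some alternative settings. Named genes were bound more often than unnamed ones (25.7% against 18.9%), and against named genes alone, with 25.6% of the others bound, the calls of the ethylene response (32.5%), late embryogenesis (55.6%), heat shock (36.5%) and bZIP (39.5%) families were lost. Over 9 alternative settings the bZIP call was lost in 7, the heat shock call in 3 and the late embryogenesis call in 2.

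Of the 5 peaks with the highest scores, 4 lay at protein-coding genes. The highest, with a score of 4.51 (chromosome 3, 11383851 to 11384549), overlapped AFP3, a member of the family of ABI5-binding proteins. A peak with a score of 4.47 (chromosome 5, 19280101 to 19280699) lay near RABA5a and AT5G47530. A further peak with a score of 4.47 (chromosome 1, 7089801 to 7090399) lay near ERD10, a dehydrin gene, and AT1G20460. The peak with a score of 4.29 (chromosome 3, 18821801 to 18822299) had no gene within 1 kb. The peak with a score of 4.24 (chromosome 3, 2308251 to 2309249) overlapped AT3G07255 and lay near AT3G07260.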

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

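LEC1-GFP peaks that reached no 1 kb flank outside a protein-coding gene were not used in the main list tests and numbered 1698 of 6356 (26.7%), a signal outside the main measurement. Some of them entered the alternative tests with wider flanks or the gene body. Of the 1698 peaks, 756 lay inside a protein-coding gene, 247 at another kind of gene and 695 (10.9% of all peaks) at no gene of the table. Their median score was 2.38, against 2.47 for peaks with a gene. No explanation was tested for these peaks.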

How the results depend on the processing

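Tests against named genes and with the gene body alone were chosen after the data were seen, and the other settings were planned, here with flanks at either gene end in place of upstream windows. Peak shares near gene ends and in gene-poor windows kept their direction and call in every setting tried. Calls for regulators, storage proteins, fatty acid and oil synthesis, late embryogenesis, photosynthesis and abscisic acid lists held in all 12 list settings, although the photosynthesis share fell to 43.1% with the midpoint or at least 50% of the peak in the flank, below the storage protein, oil body, late embryogenesis, brassinosteroid and regulator lists. List tests were Fisher's exact tests, apart from the permutation test against matched random lists, and p-values below are adjusted. With the 3178 highest-scoring peaks alone there were, by construction, fewer bound genes (3323), and 12.1% of genes outside each list were bound, with the oil body list at 33.3% (exact p = 0.145), gibberellin at 27.3% (0.0805) and brassinosteroid at 42.9% (0.0805). The gene body alone gave 3432 bound genes. The midpoint in the flank and at least 50% of the peak in the flank each gave 4899 bound genes and the same lost calls. They are therefore not separate checks. Gibberellin stood at 27.3% with 500 bp flanks (16.96% of others, 0.422) and with the midpoint or at least 50% of the peak in the flank (17.8% of others, 0.406 in both), and at 31.8% with the nearest gene only (15.4% of others, 0.114). NF-Y subunits stood at 32.0% with the midpoint and with at least 50% of the peak in the flank (17.8% of others, 0.133 in both). Against named genes, oil body genes stood at 62.5% (0.0574) and gibberellin genes at 45.5% (0.0806), and 3 families were called higher and cytochrome P450 genes were called lower (18.1% against 25.8%, 0.0458; 0.0458 to 1 over the family settings). Adjusted p over all settings ran from 0.00266 to 0.145 for oil body, 0.00515 to 0.422 for gibberellin, 0.00294 to 0.0805 for brassinosteroid and 2.58e-05 to 0.133 for NF-Y genes. The cause of the lost calls was not tested. Of single family comparisons 194 kept their call, 13 lost it and 9 gained it (cytochrome P450 genes, called lower, among them), and no result reversed. No paired analysis was possible because the labels share replicate numbers but the data are 1 peak list with no values per sample, and leaving out each replicate was not run for the same reason. Motif tests and windows upstream of transcription start sites were not run. Depth is unknown, so genes without a peak are not shown to be free of LEC1-GFP.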

Other observations

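Tests of words in gene names, of the groups in the next paragraph, of named genes as background, of ribosomal protein genes, of the LEC1 peak and of scores in the bound lists were chosen after results had been seen, whereas the tests of intergenic length and of pseudogene position were written before their results were seen. Word tests compared named genes with each other and covered 439 words, of which 10 had a higher and 4 a lower bound share (Fisher's exact test, Benjamini-Hochberg adjustment). Genes with phosphate in their name were bound at 53 of 125 (42.4%, exact adjusted p = 0.00411) and genes with dehydration in their name at 13 of 22 (59.1%, exact adjusted p = 0.0361). Cysteine-rich protein genes were bound at 12 of 127 (9.45%, exact adjusted p = 0.000580), genes with embryo in their name at 65 of 379 (17.2%, exact adjusted p = 0.00531), and genes with processing in their name at 0 of 23 (exact adjusted p = 0.0457). A word in a name does not show where a gene is active, so the embryo share is not a share of embryo-expressed genes.

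Groups behind these words were then counted by symbol, 5 groups in all with adjustment over those 5, so their p-values follow from a selection on the same data. Trehalose-phosphate synthase and phosphatase genes, which act in sugar signalling, were bound at 13 of 21 (61.9% against 25.6% of other named genes, Fisher's exact test, adjusted p = 0.00121). TPS11 had a score of 4.12, TPPG 3.96 and TPPH 3.52, whereas TPS1 had no peak. Early responsive to dehydration genes were bound at 9 of 12 (75.0%, exact adjusted p = 0.00121) and early nodulin-like protein genes at 12 of 22 (54.5%, exact adjusted p = 0.00632), with a highest score of 3.32 at ENODL2. The word nodulin-like, also at 12 of 22, had not passed adjustment over the 439 words (exact adjusted p = 0.0888). Low-molecular-weight cysteine-rich genes were bound at 9 of 80 (exact adjusted p = 0.00319). Over the 439 words, low-molecular-weight had not passed (10 of 84, exact adjusted p = 0.0641), although cysteine-rich had. Cytokinin response factors were bound at 6 of 12 (50.0%), which did not pass (exact adjusted p = 0.0893), although CRF3 had a score of 4.12.

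Photosynthesis and seed maturation genes had high bound shares. More peaks at well-studied genes did not account for the photosynthesis list, which kept an adjusted p of 1.01e-16 against named genes alone (2.63e-23 to 0.00113 over all settings), and lists matched on intergenic length left it at an adjusted p of 0.00113, the smallest that 10000 draws allowed for it. Pull-down of strongly transcribed chromatin without LEC1 remains open: ribosomal protein genes were bound at 16.4% (8.49 to 27.5%), but RNA levels and a pull-down from plants without GFP were not analysed here. LEC1 occupancy as the source of the high shares is therefore a hypothesis.

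The peak at LEC1 itself scored above 22.5% of all peaks. Extra copies of LEC1 flanking sequence from the transgene may contribute to it, and this cannot be told apart from binding at the native gene because the ends and copy number of the transgene were not used here. No biological explanation was tested.

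Genes labelled as transcribed pseudogenes were bound at 6.80% of 926 and are left out of the comparison that follows. The other genes labelled as pseudogenes were bound at 2.58% of 3917, compared with 13.1% of transfer RNA genes, 11.7% of microRNA genes and 17.7% of long noncoding RNA genes. Most of them, 3245, lay in the gene-poor windows, where 1.39% were bound against 10.8% of protein-coding genes. Which kinds of sequence carry this label was not examined, so the share describes the label and not pseudogenes in general. Position in gene-poor regions did not account for all of this: outside the gene-poor windows pseudogenes were bound at 8.33% (6.36 to 10.7%) and protein-coding genes at 22.7% (Fisher's exact test, p = 2.36e-22). Reads that map to several copies may be missing at pseudogenes, which could not be tested because the mapping settings are not given in the sources used here.

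A hypothesis tested on the same data was that peaks at genes of the 10 enriched lists score higher than peaks at other bound genes. The 151 bound loci of these lists had a median highest score of 2.76, against 2.53 for all bound genes (permutation p = 6e-05, two-sided) and 2.54 for named bound genes (permutation p = 2e-05, the smallest that 100000 draws can give). Of these loci 73.5% had a peak among the 3178 with the highest scores, against 56.5% of all bound genes. The lists entered this test because they were enriched for bound genes, and of single lists the seed regulators alone passed adjustment.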
